A study of Mus musculus with 6 samples.

How the data were processed

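RNA was sequenced in bulk from the heart ventricles of 6 mice aged 9 months, 3 labelled Fiona/dko and 3 labelled Het/Fiona, each group with 1 female and 2 males. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and made into libraries with an NEBNext Ultra II kit at a sequencing company. Whether the libraries kept strand is not given in the sources used here. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to the mouse genome build mm39 and counted per gene with featureCounts. The labels give each mouse its own number, so the replicates are separate animals. Replicate numbers used here follow the order of the samples and pair no animals.

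The authors deposited a single table of 26329 genes with a signal value per library, which is a read count per gene divided by 1 size factor per library, as the values themselves show. Every value of a library was a whole multiple of a fixed step, and 100% of values came out within 0.01 of a whole read, so whole reads were recovered by dividing by that step. Recovered reads numbered 15461876, 22758553 and 15723605 in Fiona/dko replicates 1 to 3 and 16013573, 17206959 and 15505225 in Het/Fiona replicates 1 to 3. The deposited table also holds the authors' log2 fold change, p-value and adjusted p-value per gene, from a tool that is not given in the sources used here. In it, 10725 genes (40.7%) have an adjusted p of exactly 1 and 5 have no p. A gene missing from the table or under the filter on low values was not tested. Gene positions are those of the deposited table and were read as mm39. The reference annotation at hand is of an older build and was not used.

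Because the values are normalized, the genotype test was limma 3.58.1 (R 4.3.3) with an intensity trend and robust variance on log2(value + 1), without further scaling. A fold change is a difference of mean log2 values, so it can differ from the ratio of the group means beside it, most of all at low values. Genes with a value of at least 10 in at least 3 libraries were tested, 15395 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design was written for counts or normalized values before the data were examined, and its branch for normalized values was used. Sex was tested in a model with genotype and sex. The sex-by-genotype interaction was added after the data were seen. Unless another tool is named, every adjusted p of a gene is from limma with Benjamini-Hochberg adjustment.

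The 27 gene lists (13 on the disease process and 14 on other cell types, sample quality and hormone response) were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and beside it with a correlation estimated from the data and with fry. A list needed 5 tested members. Fry's p asks whether the members move on balance in one direction and does not compare them with other genes. Single values per library were compared with a two-sided exact permutation test, which over 20 assignments of 3 against 3 cannot give a p below 0.1.

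Named genes were chosen by a rule set before the data were examined. It takes Utrn and Dmd, the 6 largest rises and 6 largest falls among called protein-coding genes whose groups did not overlap and whose higher mean was at least 50, up to 2 called members with the smallest p in each disease list (or 1 uncalled member where none was called), the called member with the smallest p in each other list, and Xist and Y-linked genes for the sex labels. Other members of the lists named in the text, and genes named in the sex and ribosomal RNA comparisons, were chosen after their values were seen. Some members of the lists are not reported here by name. Genes with near-identical copies, among them Acot1, Acot2, Entpd4b, Ccl21a, Hspa1a, Hspa1b and the hemoglobin genes, are uncertain because the counting can split their reads.

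The steps were tested on simulated data for this comparison. Counts were drawn from the real means, dispersions and library sizes, with 50 genes changed at each fold. The simulated test held 15296 genes past the filter. The test recovered 34% of genes raised 1.5-fold, 64% of those raised 2-fold, 92% of those raised 4-fold and 54% of those lowered to 0.5 of their level. Of 134 calls, 7 (5.22%) were false and 5 were members of the macrophage list, which was raised 1.5-fold as well. A genotype difference of 1.5-fold in a single gene is therefore often missed at this number of animals. No gene or list was called where nothing was changed. Genes were drawn independently of each other, so the simulation cannot show false list calls that arise from inter-gene correlation.

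The alternatives were sex as a covariate, each library left out in turn, limma-voom, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, TMM scaling of the values, no filter, a mean of at least 50, pseudocounts of 0.5 and 5, an added absolute log2 fold change of at least 1, and an adjusted p of 0.01. A term for a split of the libraries by ribosomal RNA content, the 4 libraries rich in it alone, and edgeR and DESeq2 for Utrn and Dmd were added after the data were seen. On the recovered reads, edgeR's quasi-likelihood test called 614 genes higher and 721 lower, and DESeq2 called 690 higher and 802 lower. These 1492 genes are those called in the deposited table, with log2 fold changes within 4.68e-06 of it, so DESeq2 and the deposited table are not separate checks. Figures were drawn with matplotlib 3.10.9. No library was left out of the main comparison.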

Results

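Gene expression was measured by bulk RNA sequencing in heart ventricles of 9-month-old mice, 3 Fiona/dko and 3 Het/Fiona, to ask which genes differ between hearts with the more severe cardiomyopathy (Fiona/dko) and those with the milder form (Het/Fiona). Fiona names a utrophin transgene made for skeletal muscle, and dko is the usual name for mice that lack dystrophin and utrophin. The labels do not explain Het, so whether Het/Fiona mice have dystrophin, and whether Dmd should differ, is not known here. Values are the authors' normalized read counts, from libraries of 15461876 to 22758553 recovered reads with 20410 to 21761 genes detected. Over the 15395 genes tested, Pearson's r of log2 values across genes was 0.963 to 0.970 between libraries of a genotype and 0.943 to 0.962 between genotypes. No pair of libraries agreed within sampling noise (smallest chi-square per degree of freedom, 16.5). The first principal component, with 35.6% of the variance, separated the genotypes, and the second, with 20.8%, separated females from males. The labels name no batch, but the libraries fell into a set of 2 and a set of 4 by ribosomal RNA. Fiona/dko replicate 2 and Het/Fiona replicate 3 gave 0.0358% and 0.0432% of their reads to the ribosomal RNA gene Rn18s-rs5, against 2.22% to 4.03% in the other 4. Gapdh read 2379 and 3259 in those libraries and 149 to 253 in the rest. Each set held both genotypes.

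Utrn, which encodes utrophin, was lower in all 3 Fiona/dko hearts. Its normalized count was 597 ± 6.16 in Fiona/dko and 973 ± 145 in Het/Fiona (SD, n = 3 each), a log2 fold change of -0.69 (SE 0.12, limma adjusted p = 0.00174). The libraries labelled Fiona/dko held 592, 595 and 604, and those labelled Het/Fiona held 1126, 839 and 955. Dmd, which encodes dystrophin, read 308 ± 56.3 and 374 ± 45.0, and did not pass the test (log2 fold change -0.29, SE 0.16, limma adjusted p = 0.317). Utrn (ENSMUSG00000019820) lies on chromosome 10 from 12257932 to 12745109 and Dmd (ENSMUSG00000045103) on chromosome X from 81992476 to 84249747 in mm39. Gene counts do not separate reads of a transgene or of parts of a gene outside an alteration from other reads of that gene, so they do not show whether protein was lost.

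In Fiona/dko hearts 623 genes were higher and 713 lower than in Het/Fiona hearts, and 219 of the higher and 106 of the lower changed by at least 1 on the log2 scale. Among the 6 largest rises by the naming rule were those in Gng8, a G protein gamma subunit, from 3.21 ± 2.81 to 77.4 ± 18.9 (log2 fold change 4.57, SE 0.69, adjusted p = 6.98e-04), in the collagen gene Col8a2, from 10.4 ± 4.67 to 153 ± 59.2 (3.76, SE 0.41, adjusted p = 5.48e-05), and in Ltbp2, which encodes a protein that binds fibrillin microfibrils, from 124 ± 52.8 to 1493 ± 369 (3.63, SE 0.30, adjusted p = 6.66e-04). Vgll2, a transcription cofactor, rose by 3.65, Ngef by 3.52 and the matricellular gene Ccn5 by 3.40 on the log2 scale, with adjusted p of 0.00774, 0.0373 and 0.0104. The largest falls were in Entpd4b, from 142 ± 115 to 3.24 ± 2.91, and in Acot1, an acyl-CoA thioesterase gene, from 243 ± 82.9 to 35.3 ± 15.1, with log2 fold changes of -5.18 and -2.78 and adjusted p of 6.68e-04 and 1.22e-04. The chloride channel gene Clcn1, the water channel gene Aqp4, the acyl-CoA synthetase gene Acsm5 and the protease gene Tmprss13 fell, with log2 fold changes of -2.67, -2.60, -2.57 and -2.29 (adjusted p = 7.24e-04, 0.0165, 0.00667 and 0.037). Libraries of the 2 genotypes did not overlap for 26.8% of the tested genes, against 10% by chance. The authors' deposited table calls 690 genes higher and 802 lower, and 1304 genes were called in both, all with the same sign. DESeq2 on the recovered reads called the same 1492 genes as that table and is no separate check of it. Among the 4 libraries rich in ribosomal RNA alone, 2 against 2, 276 genes were higher and 281 lower, while the other set holds 1 library of each genotype and allows no test. Calls fell to 407, 351 and 415 higher without Fiona/dko replicate 2, Fiona/dko replicate 3 and Het/Fiona replicate 3, and to 400, 461 and 399 lower without Fiona/dko replicate 3, Het/Fiona replicate 2 and Het/Fiona replicate 3. Single genes that lost their call without 1 library were Ngef (without any Fiona/dko replicate or Het/Fiona replicate 3, adjusted p = 0.0882 to 0.166, and 0.261 in the authors' table), Tmprss13 (without Fiona/dko replicate 1 or 3 or Het/Fiona replicate 1 or 2, adjusted p = 0.116 to 0.146), Aqp4 (without Het/Fiona replicate 1 or 3, adjusted p = 0.0749 and 0.07) and Acsm5 (without Het/Fiona replicate 3, adjusted p = 0.0522).

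**Figure D1:**
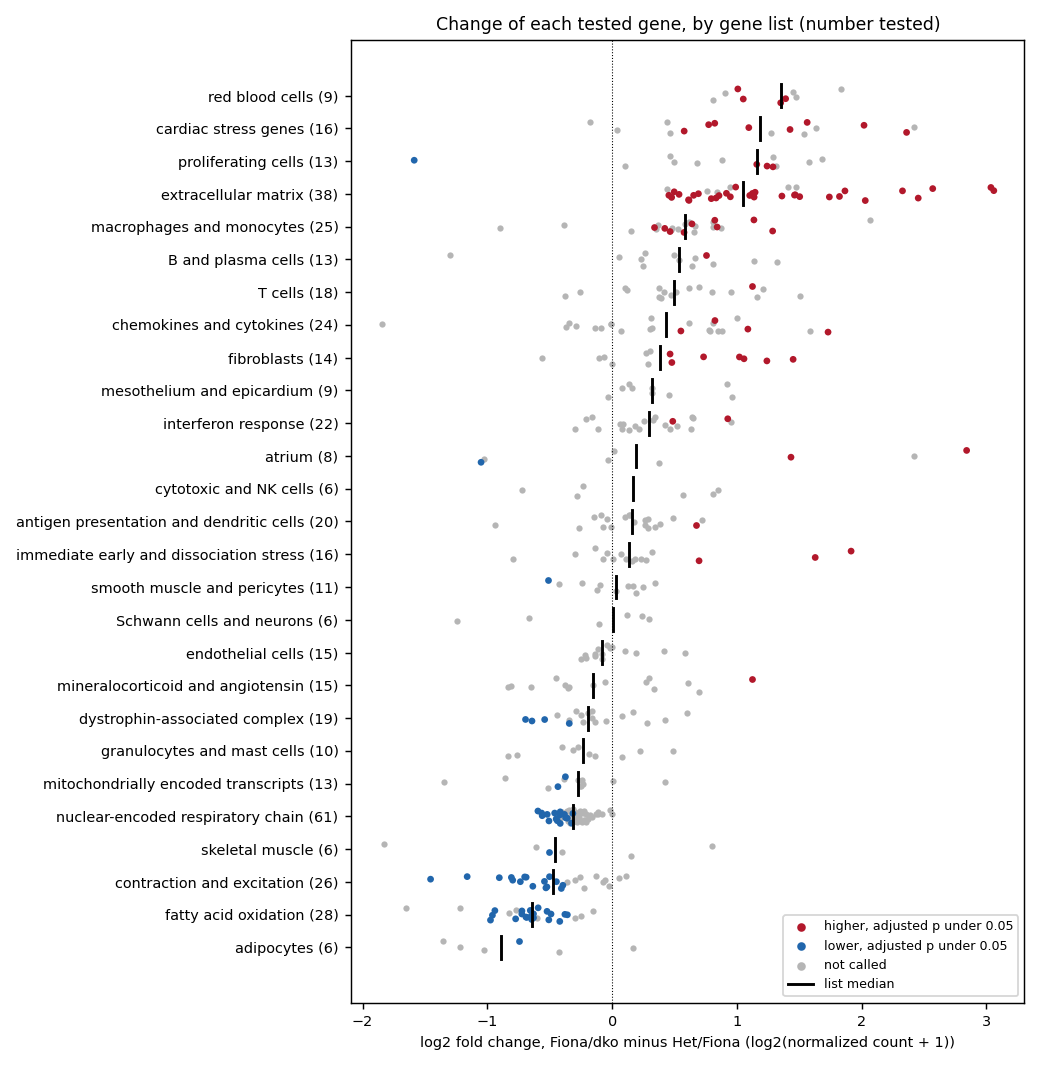
Log2 fold change of each tested gene (Fiona/dko minus Het/Fiona, x axis, on the log2(normalized count + 1) scale) in each of 27 gene lists (y axis, with the number of genes tested). Red and blue points passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment as higher or lower, grey points did not, and black bars are list medians. All 38 extracellular matrix genes lie above 0 and all 28 fatty acid oxidation genes lie below 0.

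Genes of the extracellular matrix rose together in Fiona/dko hearts. Of 38 tested, 31 rose, 0 fell and 7 did not pass, and 38 rose when adjusted over the list alone. The median log2 fold change was 1.05. Comp, a cartilage and tendon matrix gene, rose from 194 ± 33.7 to 1628 ± 288 (log2 fold change 3.06, SE 0.15, adjusted p = 3.89e-08), and the microfibril gene Mfap5 rose from 866 ± 164 to 2428 ± 122 (2.83-fold, adjusted p = 4.89e-06). The collagen gene Col12a1 rose by 3.04 and Timp1, an inhibitor of matrix proteases, by 2.03 on the log2 scale. Postn and Mfap4, also called higher, were in addition 0.89 and 0.90 higher on the log2 scale in the 4 libraries rich in ribosomal RNA than in the other 2. Of 14 fibroblast markers 7 rose and 0 fell, also 7 and 0 when adjusted over the list alone, with a median of 0.38. Pi16 led them, from 1823 ± 250.0 to 4282 ± 148 (1.24, SE 0.11, adjusted p = 7.78e-06). Camera called the matrix list (adjusted p = 7.45e-40) and the fibroblast list (adjusted p = 4.09e-05) higher. Neither call was kept with an estimated correlation (adjusted p = 0.114 and 0.18).

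Genes that heart muscle turns on under load or injury also rose. Of 16 cardiac stress genes tested 8 rose, 0 fell and 8 did not pass, and 12 rose when adjusted over the list alone, with a median log2 fold change of 1.19. Myh7, the slow myosin heavy chain, rose from 4427 ± 179 to 18732 ± 6425 (2.02, SE 0.26, adjusted p = 0.00693), and Ankrd1, a stretch-responsive sarcomere protein gene, from 14653 ± 2581 to 40039 ± 11578 (1.43, SE 0.21, adjusted p = 0.00502). Gdf15, a secreted stress cytokine, rose by 2.36 and Atf3 by 0.77. The natriuretic peptide genes Nppa and Nppb had log2 fold changes of 2.42 and 1.54 but did not pass (adjusted p = 0.064 and 0.0711). With genotype in the model, Nppb was also higher in males (log2 difference 0.79, limma adjusted p = 3.26e-04). That sex difference adds to its spread in the genotype test, which has no term for sex. Camera called the list higher (adjusted p = 5.79e-13), though not with an estimated correlation (adjusted p = 0.18). Myh7 lost its call in 2 of the 12 settings followed for it, among them without Het/Fiona replicate 1 (adjusted p = 0.0579). Its highest adjusted p was 0.124.

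Genes of contraction and electrical excitation fell, while markers of fibroblasts, macrophages and red cells rose by medians of 0.38, 0.58 and 1.35 on the log2 scale and those of endothelial cells had a median of -0.08. Of 26 tested 16 fell, 0 rose and 10 did not pass, and 19 fell when adjusted over the list alone, with a median log2 fold change of -0.47. Scn4b, a sodium channel subunit gene, fell from 563 ± 134 to 247 ± 23.3 (log2 fold change -1.16, SE 0.16, adjusted p = 4.51e-04), and Ryr2, the calcium release channel of the sarcoplasmic reticulum, from 11964 ± 1267 to 7334 ± 338 (-0.70, SE 0.10, adjusted p = 5.62e-04). Myh6, the fast myosin heavy chain of the adult mouse ventricle, fell by 0.80, the calcium pump gene Atp2a2 by 0.74 and the potassium channel gene Kcnj2 by 0.90 on the log2 scale. Camera called the list lower (adjusted p = 3.90e-11), and it was the single list of 27 whose call was kept with an estimated correlation (adjusted p = 0.042).

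Most genes of fatty acid oxidation and some of the respiratory chain fell as well, beside the same rises of other cell types. Of 28 fatty acid oxidation genes tested 20 fell, 0 rose and 8 did not pass, and 24 fell when adjusted over the list alone, with a median of -0.65. Acaa2, which carries out the last step of mitochondrial beta-oxidation, fell from 12293 ± 341 to 6369 ± 960.4 (-0.96, SE 0.11, adjusted p = 1.07e-04), and Acot2, a mitochondrial acyl-CoA thioesterase gene, from 1058 ± 162 to 535 ± 37.8 (-0.98, SE 0.12, adjusted p = 2.12e-04). Of 61 nuclear genes of the respiratory chain 16 fell, 0 rose and 45 did not pass, and 29 fell when adjusted over the list alone, with a median of -0.31. Sdha of complex II fell by 0.60 and Uqcrc1 of complex III by 0.56 on the log2 scale (SE 0.10 and 0.09, adjusted p = 0.00114 and 0.00137). Of 13 transcripts encoded in mitochondrial DNA 2 fell, mt-Nd2 and mt-Nd5, by 0.43 and 0.37, and 3 fell when adjusted over the list alone, with a median of -0.27. Together these transcripts took 21.9% ± 1.70 of reads in Fiona/dko and 25.8% ± 3.53 in Het/Fiona (SD, n = 3 each, two-sided exact permutation p = 0.2). Camera called the lists lower with adjusted p = 4.63e-23 for fatty acid oxidation, 1.68e-16 for the nuclear respiratory chain and 0.0277 for mitochondrial DNA. None of these was called with an estimated correlation (adjusted p = 0.0919, 0.329 and 0.641), and by fry the nuclear respiratory chain and mitochondrial DNA lists were not called either (adjusted p = 0.0896 and 0.312). The mitochondrial DNA list was not called without Fiona/dko replicate 1, Fiona/dko replicate 3 or Het/Fiona replicate 2 (adjusted p = 0.121, 0.164 and 0.315), and mt-Nd2 passed only without Het/Fiona replicate 1 and not without any other library (adjusted p = 0.1 to 0.161).

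In the dystrophin-associated complex 4 of 19 tested genes fell, 0 rose and 15 did not pass, against 5 lower and 1 higher when adjusted over the list alone, with a median of -0.20. Among the genes that fell were Utrn itself, the sarcoglycan gene Sgca and the laminin receptor gene Itga7. Sgca fell from 1623 ± 114 to 1040 ± 86.7 (log2 fold change -0.64, SE 0.10, adjusted p = 0.00114). Camera called the list lower (adjusted p = 0.00919), but not with an estimated correlation (adjusted p = 0.261). The list holds Utrn and Dmd, to which the genotype names refer, and it was not tested without them. Its call is therefore not separate from the fall of Utrn.

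Macrophage genes were higher in Fiona/dko hearts, and T cell genes were sparse in both genotypes. Of 25 macrophage and monocyte genes 9 rose, 0 fell and 16 did not pass, against 19 higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.58. Lgals3, which encodes galectin-3, rose from 281 ± 75.8 to 675 ± 99.2 (1.29, SE 0.19, adjusted p = 9.18e-04) and the Fc receptor gene Fcgr1 from 70.5 ± 6.24 to 156 ± 13.6 (1.14, SE 0.23, adjusted p = 0.00498). C1qa, Mrc1 and Csf1r rose by 0.64, 0.42 and 0.34. Of 18 T cell genes tested 1 rose over all genes and 0 when adjusted over the list alone, with a median of 0.49. It was the interleukin-7 receptor gene Il7r, from 40.2 ± 13.9 to 85.4 ± 7.06 (1.12, SE 0.33, adjusted p = 0.0435). The T cell list took 36.0 ± 8.43 CPM of recovered reads in Fiona/dko and 22.1 ± 5.13 in Het/Fiona (n = 3 each, two-sided exact permutation p = 0.1, the smallest possible), or 302 to 808 reads per library. Hemoglobin transcripts took 1.12% ± 0.423 of reads in Fiona/dko and 0.368% ± 0.0345 in Het/Fiona (n = 3 each, two-sided exact permutation p = 0.1). Camera called both lists higher, with adjusted p = 2.83e-10 for macrophages and 0.0345 for T cells. Neither call was kept with an estimated correlation (adjusted p = 0.18 and 0.334). The T cell list was not called without Fiona/dko replicate 1, Fiona/dko replicate 2, Het/Fiona replicate 2 or Het/Fiona replicate 3 (adjusted p = 0.124, 0.0533, 0.0803 and 0.0652) or by fry (adjusted p = 0.0912), and Il7r passed only without Het/Fiona replicate 1 and not without any other library (adjusted p = 0.083 to 0.145).

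Chemokine, interferon and B cell lists were called higher on few genes, beside the same hemoglobin difference of 1.12% against 0.368% of reads. Of 24 chemokine and cytokine genes tested 4 rose and 0 fell, against 4 higher and 2 lower when adjusted over the list alone, with a median of 0.43. The lymphoid chemokine gene Ccl21a rose from 1627 ± 75.8 to 3462 ± 224 (log2 fold change 1.09, SE 0.10, adjusted p = 7.85e-06), the alarmin gene Il33 by 0.82 (SE 0.17, adjusted p = 0.00565), and Cxcl5 and Cxcl16 by 1.73 and 0.55. Of 22 interferon response genes 2 rose and 0 fell, and the same numbers held when adjusted over the list alone, with a median of 0.29. They were Bst2, at 0.49, and the nucleic acid sensor gene Zbp1, at 0.93. Of 13 B and plasma cell genes the kinase gene Blk alone rose, by 0.75, with 1 higher and 0 lower when adjusted over the list alone and a median of 0.54. Camera gave these lists adjusted p = 0.00919, 0.0086 and 0.0218. With an estimated correlation they were not called (adjusted p = 0.551, 0.551 and 0.18), and by fry the chemokine and interferon lists were not called either (adjusted p = 0.282 and 0.312). The B and plasma cell list was not called with the stricter filter (adjusted p = 0.0634). Of 20 antigen presentation genes 1 rose, Psmb9 of the immunoproteasome, by 0.67, also 1 when adjusted over the list alone, with a median of 0.16. Of 6 cytotoxic and NK cell genes 0 rose or fell on either adjustment, with a median of 0.17, and Klrk1 read 40.4 ± 14.4 and 24.9 ± 17.2 (adjusted p = 0.364). Camera called neither list (adjusted p = 0.12 and 0.68). The chemokine list was not called without Het/Fiona replicate 1 (adjusted p = 0.263) and the interferon list not without Fiona/dko replicate 1 (adjusted p = 0.355). The antigen presentation list was called without Fiona/dko replicate 3 or Het/Fiona replicate 1 (adjusted p = 0.00227 and 0.0305). Blk passed only without Fiona/dko replicate 1 and not without any other library (adjusted p = 0.0795 to 0.173). Bst2 did not pass without Fiona/dko replicate 1 or 2 or Het/Fiona replicate 2 or 3 (adjusted p = 0.0504 to 0.117), Zbp1 not without replicate 1 or 3 of either genotype (adjusted p = 0.0817 to 0.13), and Psmb9 not without Fiona/dko replicate 1 or Het/Fiona replicate 2 or 3 (adjusted p = 0.0695 to 0.0924).

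**Figure D2:**
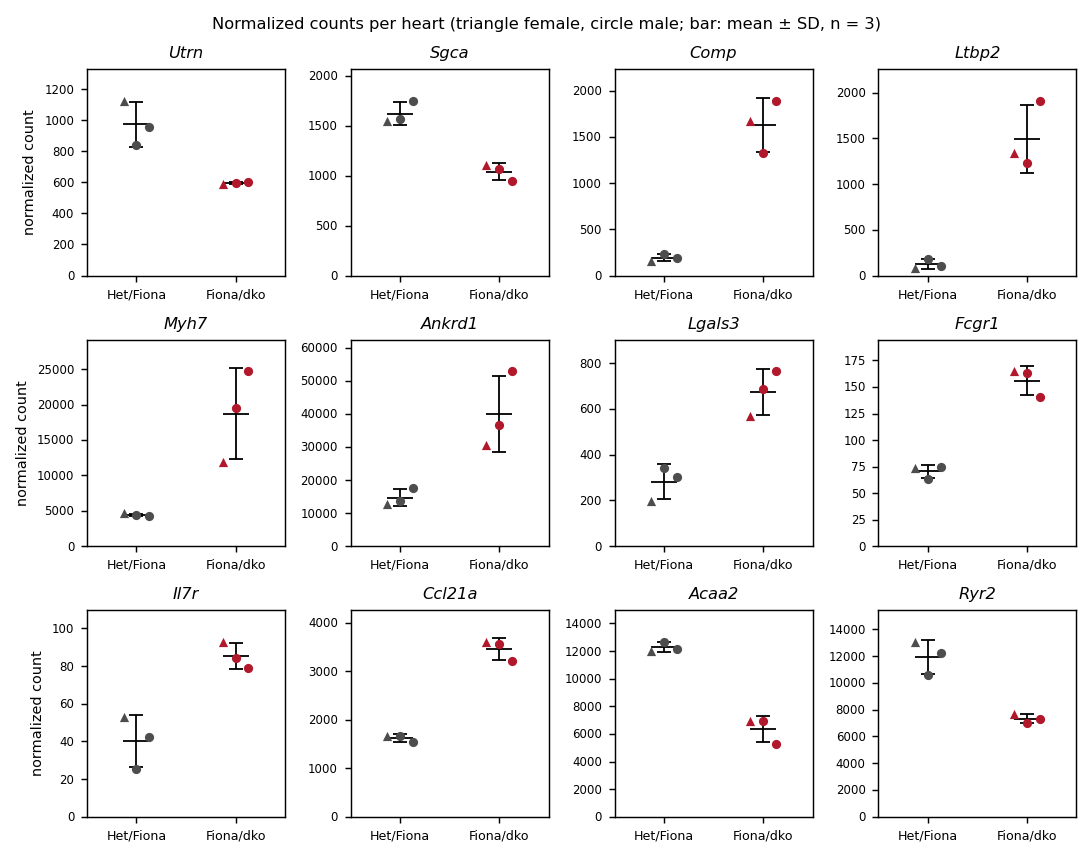
Normalized counts (y axis, starting at 0) of 12 genes in each heart, by genotype (x axis). Triangles are females, circles are males, and bars give mean and SD (n = 3). For Utrn the Fiona/dko hearts lie between 592 and 604 and the Het/Fiona hearts between 839 and 1126, and for each of the 12 genes the genotypes do not overlap.

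Among lists for other cell types and tissue handling, red cell genes rose. Of 9 tested 4 rose (among them Hba-a1, Alas2 and Bpgm) and 0 fell, against 5 and 0 when adjusted over the list alone, with a median log2 fold change of 1.35. Alas2, the first enzyme of heme synthesis in red cells, rose from 1304 ± 308 to 3382 ± 506 (1.39, SE 0.17, adjusted p = 9.01e-04). Of 13 proliferation genes tested 12 had a positive change. Mki67, Top2a and Rrm2 rose by 1.24, 1.16 and 1.29 while the kinetochore gene Cenpf fell by 1.59 (SE 0.20, adjusted p = 1.91e-04), against 4 higher and 1 lower when adjusted over the list alone, with a median of 1.16. Of 16 immediate early and dissociation genes 3 rose and 0 fell on either adjustment, with a median of 0.13, and the members that rose were the heat shock genes Hspa1a, Hspa1b and Hsp90aa1, by 1.92, 1.63 and 0.70. Camera called these lists higher with adjusted p = 5.44e-08, 0.00622 and 0.0442. With an estimated correlation they were not called (adjusted p = 0.18, 0.18 and 0.204). The immediate early list was not called without Fiona/dko replicate 1, Fiona/dko replicate 2 or Het/Fiona replicate 2 (adjusted p = 0.0761, 0.0515 and 0.157), nor with limma-voom (adjusted p = 0.0531).

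The remaining lists were not called by camera, and fry called the skeletal muscle list alone among them lower (adjusted p = 0.0351). Endothelial genes had a median log2 fold change of -0.08 over 15 genes, smooth muscle and pericyte genes 0.03 over 11 and granulocyte and mast cell genes -0.23 over 10, with camera adjusted p = 0.68, 0.68 and 0.576. For adipocyte (6 genes), skeletal muscle (6), mesothelium (9), atrium (8), Schwann cell and neuron (6) and mineralocorticoid and angiotensin (15) genes the adjusted p were 0.0629, 0.186, 0.157, 0.152, 0.68 and 0.965, with medians of -0.89, -0.46, 0.32, 0.19, 0.01 and -0.15. The camera direction was down for smooth muscle and for Schwann cells although their medians lay above 0. Single members that fell were Abcc9 (-0.51) among smooth muscle and pericyte genes, Plin4 (-0.75) among adipocyte genes, Ckm (-0.51) among skeletal muscle genes and Kcnj3 (-1.05) among atrial genes. Dkk3 and Myl4 of the atrial list rose by 2.84 and 1.43. When adjusted over the list alone 3 atrial genes were higher and 1 lower, and in the adipocyte, skeletal muscle and smooth muscle lists 1 gene each was lower. The mineralocorticoid list had 1 higher, and the endothelial, granulocyte, mesothelium and Schwann cell lists had 0 of either. The adipocyte list was called lower without Fiona/dko replicate 1, without a filter and with the ribosomal RNA term (adjusted p = 0.0332, 0.0217 and 0.0499), and the mesothelium list without Fiona/dko replicate 2 or Het/Fiona replicate 1 (adjusted p = 0.00898 and 0.0352).

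Between the sexes, with genotype in the model, 42 genes were higher and 12 lower in the 4 males than in the 2 females. The filter asks for a value of at least 10 in at least 3 libraries. A gene read in the 2 females alone, such as Xist, was therefore not tested, so the counts of the 2 directions are not comparable. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were among them, and 4 were on the X chromosome. Eif2s3y read 0 in each female and 899 to 954 in the males, and Xist read 5298 and 5003 in the females and 4.76 on average in the males, so each library matched its sex label. The liver and plasma protein gene Hp was higher in males (166 against 23.5 on average, log2 difference 2.78, SE 0.26, adjusted p = 1.94e-05), as was Plxna2 (1358 against 589, log2 difference 1.19, adjusted p = 1.46e-05). Col14a1 and Ptn were lower in males by a log2 difference of -0.84 and -1.03. With 1 female per genotype these differences rest on few animals, and the females were both in the set rich in ribosomal RNA. The count was 86 without Fiona/dko replicate 1, 90 without Fiona/dko replicate 3 and 24 without Het/Fiona replicate 1. Without either replicate 1 a single female is left, and its spread is taken from the males.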

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

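The interaction test was chosen after the data were seen. In a limma model with a sex-by-genotype interaction and Benjamini-Hochberg adjustment, 2 genes had a genotype difference that differed between males and females. They were Gm28437, with a log2 fold change of -1.37 in males and 0.06 in the female pair, and Ndufa12-ps, with -1.19 and 0.41 (adjusted p = 0.0466 for each). Gm28437 read 7429 in the Fiona/dko female and 5981 and 7116 in the Fiona/dko males, against 7138 in the Het/Fiona female and 16219 and 17565 in the Het/Fiona males. Neither gene was among those called between genotypes, and the fit rests on 1 female per genotype and 2 residual degrees of freedom. Reads of gene copies such as these are uncertain, because counting can split them between near-identical loci.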

How the results depend on the processing

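The ribosomal RNA term, the 4 libraries rich in it alone, and edgeR and DESeq2 for Utrn and Dmd were chosen after the data were seen. Counts of genes higher and lower in Fiona/dko stayed within 1.5 times of 623 and 713 with sex as a covariate, limma-voom, edgeR, DESeq2, TMM scaling, either filter, either pseudocount and the ribosomal RNA term. Sex and the ribosomal RNA term are balanced over the genotypes, so they leave fold changes as they are and alter their error alone. They were 276 and 281 in the 4 libraries (fewer samples), 219 and 106 with a log2 fold change of at least 1 and 267 and 318 at an adjusted p of 0.01 (stricter thresholds), and 351 to 541 and 399 to 623 with 1 library left out. Utrn passed and Dmd did not with sex, limma-voom, edgeR, DESeq2, TMM scaling, no filter, the ribosomal RNA term, the 4 libraries and each library left out. With 1 library left out their log2 fold changes were -0.80 to -0.58 and -0.43 to -0.19, and in the 4 libraries -0.70 and -0.44. Lists called numbered 8 to 12 higher and 4 to 5 lower with 1 library left out, and 0 and 1 with an estimated correlation. The B and plasma cell, proliferation and immediate early lists lost their calls there at estimated correlations of -0.05, -0.03 and -0.02. The contraction list, which kept its call, went from adjusted p = 3.90e-11 to 0.042 at an estimated correlation of -0.014. Correlated members therefore do not account for each lost call, and what else weakens calls in this setting was not tested. Apart from the estimated correlation 9 of the 16 called lists kept their call throughout, and no called list changed direction. The T cell list had adjusted p = 0.00683 to 0.124 with 1 library left out, 0.0534 without a filter, 0.169 in the 4 libraries, 0.334 with an estimated correlation and 0.0912 by fry, and too few members for the stricter filter. The uncalled lists that changed direction had adjusted p = 0.682 to 0.963 (mineralocorticoid), 0.376 to 0.941 (smooth muscle), 0.503 to 0.891 (Schwann cell), 0.323 to 0.962 (cytotoxic) and 0.269 to 0.901 (granulocyte) with 1 library left out, 0.983 (granulocyte) and 0.863 (mineralocorticoid) with the stricter filter, and 0.999 (granulocyte), 0.999 (endothelial) and 0.748 (mineralocorticoid) in the 4 libraries. Of 42 called named genes apart from Utrn, 23 kept their call and none of the 43 followed changed sign with sex, limma-voom, TMM scaling, no filter, the ribosomal RNA term, the 4 libraries and each library left out, where tested. Gng8 and Entpd4b fell under the filter in 3 leave-one-out settings each. Ccn5, Entpd4b, Ankrd1, Fcgr1, Abcc9, Ckm and Hspa1a kept their call with each library left out, where tested, but lost it in 1 other setting. Their highest adjusted p were 0.124, 0.0897, 0.057, 0.0561, 0.0561, 0.1 and 0.0857. Genes differing between sexes numbered 24 to 90 with 1 library left out and 286 without a filter. The cause of other changes was not tested. Genes with low values, most T cell genes among them, are those that depth limits most.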

Other observations

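The tests of blood, of the ribosomal RNA split, of cell shares and of the DNA around Utrn were chosen after the results were seen, while the clock genes, the amino acid response genes and the regroupings of the libraries were set before. What would count for the blood and cell share explanations was made stricter after the values were seen, and the readings of the clock and amino acid response tests were changed then. Earlier tests of the split, a term for it in the model and the sign of changes in the other 2 libraries, were replaced, since the design fixes what they can show. Of 12 clock genes Dbp, an output gene of the clock, passed over all genes and was lower in Fiona/dko hearts (log2 fold change -0.59, SE 0.13, limma adjusted p = 0.00922), and 4 did when adjusted over the list alone. Tef, Nr1d1 and Nr1d2 had log2 fold changes of -0.36, -0.41 and -0.30 with adjusted p of 0.0672, 0.0893 and 0.0706, while Arntl and Clock had 0.09 and 0.04. Among 17 genes of the amino acid and integrated stress response, Ddit3 rose from 270.2 ± 18.0 to 438 ± 72.6 (log2 fold change 0.68, SE 0.15, limma adjusted p = 0.01) and Atf5 from 1085 ± 244 to 1571 ± 98.6 (0.55, SE 0.13, limma adjusted p = 0.0187).

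In Fiona/dko 16 of 26 contraction genes, 20 of 28 fatty acid oxidation genes and 16 of 61 nuclear respiratory chain genes fell. Of 38 matrix genes 31 rose. Of these lists the contraction list alone kept its call with an estimated correlation. A smaller share of cardiomyocytes in the tissue would raise the markers of other cell types alike only if those cells kept their proportions. Fibroblast genes rose more than endothelial genes, by 0.469 on the log2 scale (95% interval 0.136 to 0.803 from the spread between hearts). This argues against such an even rise as the whole cause. It cannot decide on a smaller share with fibroblasts in place of cardiomyocytes, which need not raise endothelial genes. A change in the fibroblasts themselves also stays open. A different time of dissection could also lower metabolic genes. With 1 of 12 clock genes past the threshold the count met the bound set against this explanation, but that bound was too loose, because 4 passed with sex as a covariate and 4 when adjusted over the list alone, so the hour of dissection and the genotype cannot be told apart for these genes. The genotype difference itself remains open as a biological explanation.

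Camera called the red cell, macrophage, T cell, B and plasma cell, chemokine and interferon lists higher in Fiona/dko. It did not call the antigen presentation, cytotoxic and granulocyte lists, and none of the calls was kept with an estimated correlation. Blood left in the tissue may account for part of this. If so, granulocyte genes abundant in blood (S100a8, S100a9, Retnlg, Cxcr2 and Csf3r) would rise by about the red cell median of 1.35, and their mean difference was -0.161 on the log2 scale. Its 95% interval of -1.80 to 1.48 just includes that rise, so blood and infiltrating cells cannot be told apart here with 3 hearts per genotype. S100a8 also differed across the ribosomal RNA split.

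Fiona/dko replicate 2 and Het/Fiona replicate 3 stood apart in ribosomal RNA and Gapdh. A difference in library preparation is a candidate source of that split, and 10 genes differed across it, among them Gapdh, Rn18s-rs5, mt-Rnr1, Postn and S100a8. The split is balanced over the genotypes, so a shift it adds to a gene cancels from the genotype fold change. Within the 4 libraries rich in ribosomal RNA, where the split cannot act, limma called 557 genes between genotypes. That argues against the split as the whole source of the genotype calls. Of these genes 519 (38.85% of 1336) were also called over all 6, in a fit that shares the 4 libraries. The 2 other groupings of the 4 called 0 (135 and 332 genes at an unadjusted limma p under 0.05, and 2424 for the genotypes). Both mix the genotypes on each side, so a genotype difference adds to their spread and they are no control. With the split as a term 1249 of the 1336 were still called. A balanced term leaves fold changes as they are, so that count does not bear on the question. No biological explanation of the split was tested.

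The real grouping called 1336 genes and 16 lists. Of the 10 ways to split the 6 libraries 3 against 3, it alone called as many genes and as many lists. The others called 0 genes each but 4 to 12 lists, so camera at the preset correlation called lists in every split. Each other split mixes the genotypes on both sides, so a genotype difference adds to its spread and makes gene calls unlikely. The splits are too few for a share under 0.05.

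With Gdf15 and Atf3 higher in Fiona/dko, an integrated stress response of the amino acid kind may be at work. Camera gave its 17 genes p = 0.124 (p = 0.243 with an estimated correlation) and a median log2 fold change of 0.22. In limma 2 of them passed as higher, Ddit3 and Atf5, and 0 as lower. Members that did not pass moved both ways. Aldh1l2, Phgdh and Shmt2 had log2 fold changes of -1.10, -0.79 and -0.32, while Sesn2, Mthfd2 and Trib3 had 0.75, 0.61 and 0.55. A p of 0.05 or more had been set as evidence against the explanation, which was wrong because such a p sets no bound and the median exceeded the 0.2 that the explanation asked for, so the question stays open. Within 10 Mb of Utrn 9 of 82 tested genes were called (11% against 8.66% elsewhere). DNA flanking the altered locus may differ between the genotypes, and with a one-sided Fisher's exact p of 0.28 and an odds ratio of 1.30 (95% interval 0.571 to 2.61) neither an excess nor its absence was shown.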
